A study of Mus musculus with 8 samples.

How the data were processed

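The material was 8 single-cell libraries of mouse glioblastoma cells, 4 of the GFP high and 4 of the GFP low fraction, made with droplet 3' chemistry that counts UMIs after papain dissociation and sorting on tdTomato and GFP, per the labels' protocols. The authors deposited 1 filtered matrix of UMI counts per library, with 31056 features that include the transgenes Tdtomato, eGFP and EGFRvIII. Per the submitters' processing notes, the reads were processed with Cell Ranger 5.0.1 against mm10; the annotation is not given in the sources used here. The values are whole numbers with a different total in every library, from 7646764 to 52307053 UMIs, so they were treated as raw counts, and 0 columns lacked a sample. Each library's fraction, number and sex come from the labels. These number the replicates and give their sex but do not say that each number is a separate animal, so p-values measure only the spread between these libraries. Within a fraction, the counts of any pair of libraries differed by far more than sampling noise, so no library was taken for a copy of another; this does not show that they came from separate animals.

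The comparisons, tests, gene lists, marker lists and rule for named genes were fixed before the data were examined, except where a choice is said to come later. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs, which 17220 of 19171 barcodes passed. Doublets were removed as the cells of highest Scrublet score in each library, 0.8% for each 1000 barcodes, 421 cells or 2.45% of those that passed. The other 16799 cells were clustered with scanpy 1.11.5 and igraph 0.11.9 in Python 3.11.15 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5) into 11 clusters. A cluster took a name if at least 3 markers of that type were among its 100 leading genes by fold and at least 1 was among the first 10. A cluster of 149 immune cells was set apart and the 16650 cells of the other clusters are called neural-lineage cells. The names rest on markers alone and were rebuilt here. No correction for free RNA was applied: C1qa was at 3867 CPM in immune cells and at 0.791 and 1.37 CPM in neural-lineage cells of GFP high and GFP low.

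UMI counts were summed per library over the cells of a comparison and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood F test, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are scaled to a total of 1e6 UMIs of those cells after TMM scaling, and log2 differences are GFP high minus GFP low with edgeR's standard error. Classes were tested where at least 3 libraries per fraction held at least 20 cells. For cycling calls, each neural-lineage cell of at least 2000 UMIs was thinned to 2000 (71 GFP high and 79 GFP low cells were shallower and left out), and 7586 cells with 4 or more UMIs of the G1/S and G2/M lists were called cycling. Of all thinned cells 5516 held 3 or 4, next to the threshold. Shares and RNA content were compared by exact permutation of the library labels. Differences between classes and between sexes were tested as interaction terms, the first with library as a block.

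The 32 lists covered the cell cycle (G1/S, G2/M, inhibitors and pocket proteins, chromatin and histones), stem cell states (quiescent and astrocyte, activated), glioblastoma states (AC-like, OPC-like, NPC-like, MES-like, hypoxia with MES-like hypoxia), metabolism (glycolysis, oxidative phosphorylation, cholesterol synthesis, fatty acid oxidation), ribosomes (ribosomal proteins, biogenesis), stress (immediate early, heat shock, unfolded protein response, p53 targets), immunity (interferon, antigen presentation), signalling (Notch, BMP and TGF-beta, Wnt, growth factor targets), matrix, adhesion, myelin, cilium and lysosome. Some genes stand in more than 1 list, and 2 symbols matched no feature. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, with an estimated correlation and fry beside it. Camera compares a list with all other genes, while fry tests it against no change. Named genes are the 8 largest increases and 8 largest decreases past the threshold with at least 20 CPM in the higher fraction and no overlap between fractions (4 and 4 in other comparisons), the 3 most abundant members past the threshold of each list that passed, the 2 most abundant of each other list, and a fixed set of markers and reporters. Symbols of the form Gm and a number, or ending in Rik, were left out. Members of lists named beyond this rule were named after their values were seen, and genes that define a class are not given as results within it. A few genes are not reported here. Coordinates are 1-based, from GENCODE vM21 on GRCm38, the same assembly as mm10, and 127 of 129 named genes matched it by Ensembl ID.

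Each test was first run on simulated data made from the real means and library sizes. For neural-lineage cells, with 13585 genes, edgeR found 41.8% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 97.0% of those changed 4-fold, and 3.29% of its calls were unchanged genes (11.2% for DESeq2). In the other edgeR fits unchanged genes were 11 of 160 calls with every cell, 12 of 165 in non-cycling cells, 12 of 171 in the astrocyte-like class, 5 of 143, 8 of 96, 16 of 160 and 3 of 71 in clusters 2, 5, 7 and 8, 15 of 139 in the mature-oligodendrocyte-like class, 7 of 152 in the proliferating class, 13 of 138 for the class interaction and 9 of 68 for the sex interaction. For cluster 8, with 7731 genes, it found 13 of 67 genes changed 2-fold and 55 of 66 changed 4-fold. All 3 list tests found 3 of 3 shifted lists and 0 of 22 others. The simulated genes were drawn independently of each other. The result therefore says nothing of false list calls that arise from correlation between genes.

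The replicate numbers were checked for pairing. Deviations from the fraction means correlated between same-numbered libraries at 0.42, 0.21, 0.27 and 0.33 for replicates 1 to 4, and at 0.34, 0.12, 0.19 and 0.22 without sex-linked genes. All lie above 0.1, so the numbers were taken to pair the libraries, a pairing that comes from the labels' numbers and this check. Libraries of different number also passed 0.1 over all genes, GFP high 4 with GFP low 3 (0.15) and GFP high 1 with GFP low 2 (0.11). Without sex-linked genes the highest such value was 0.09, for GFP high 3 with GFP low 2. The cutoff alone therefore does not set same-numbered libraries apart. With the replicate block 4201 genes passed in neural-lineage cells, against 3362 without it.

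Alternatives were DESeq2 size factors (RLE), the DESeq2 1.42.0 Wald test, no filter on low counts, the replicate block, sex as a covariate, each library left out, counts thinned to the smallest total of 7332750 UMIs, a strict cell filter (1000 genes, 2000 UMIs, 10% mitochondrial), every deposited barcode, doublets kept, Leiden resolution 1.0, 300 cells drawn per library, and cycling thresholds of 2 and 8 UMIs. Chosen after seeing the data were the fits without 14 cells of at least 4 vascular markers, without cluster 5, with lists in cells below 8 cycle UMIs, with the block and an estimated correlation together, of the larger oligodendrocyte cluster alone, and of the interaction tests with each library left out. Shares of the neural clusters are not compared, because several of the genes that define each cluster differ between the fractions. Other packages were anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.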

Results

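Single-cell RNA sequencing was carried out on mouse glioblastoma cells that carried tdTomato and a histone H2B-GFP fusion. H2B-GFP is a label that is diluted each time a cell divides, so cells that divide rarely keep more of it. Dissociated tumours were sorted on tdTomato and GFP into a GFP high fraction, which the study calls slow cycling, and a GFP low fraction of actively dividing cells. There were 4 droplet libraries per fraction, numbered 1 to 4, of which replicates 1 and 2 came from males and replicates 3 and 4 from females. The GFP high libraries held 19255986, 22309166, 17374344 and 52307053 unique molecular identifiers (UMIs, each marking 1 captured RNA molecule) in 1803, 2367, 1841 and 4711 barcodes. The GFP low libraries held 39237645, 7646764, 8990351 and 44726940 UMIs in 3369, 373, 652 and 4055 barcodes. After filtering, 1493, 2041, 1508 and 4307 neural-lineage cells remained in GFP high and 2928, 293, 516 and 3564 in GFP low, so GFP low replicates 2 and 3 are the least precise libraries.

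The sex labels and the reporters were looked at first. Xist, the RNA that silences an X chromosome in females, had 22396, 43755, 8772 and 28961 UMIs in the female libraries and 1, 7, 7 and 0 in the male ones. Ddx3y, a gene on the Y chromosome, had 1057, 1076, 1480 and 368 UMIs in the male libraries and 0 in each of the 4 female libraries. Tdtomato RNA was at 2239 ± 346 CPM (UMI counts scaled to a library total of 1e6; mean ± SD, n = 4 libraries) in GFP high and 2197 ± 713 CPM in GFP low neural-lineage cells. eGFP RNA was at 40.0 ± 6.2 and 28.7 ± 14.2 CPM, a log2 difference of 0.44 that did not pass the test (edgeR adjusted p = 0.328); the sort acted on GFP protein, not RNA.

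The first question was whether the fraction sorted as slow cycling held fewer cycling cells. Each neural-lineage cell was thinned to 2000 UMIs and called cycling if at least 4 of them came from genes of DNA replication or mitosis. The cycling share was 43.7 ± 3.69% in GFP high and 49.4 ± 2.23% in GFP low (SD, n = 4), and all 4 GFP high libraries lay below all 4 GFP low libraries. This difference of -5.76 percentage points had an exact permutation p of 0.0286 (two-sided), the smallest that relabelling 4 against 4 libraries can give. Cells with a strong cycling signature, at least 8 such UMIs of 2000, made up 7.37 ± 1.78% of GFP high and 18.2 ± 2.41% of GFP low (exact permutation p = 0.0286). Cycling cells were thus present in both fractions, and the difference was larger at this higher threshold. The share moved with the threshold. At 2 or more UMIs the difference was -0.174 points (exact p = 0.914), and without thinning it was -0.203 points (exact p = 0.8286). With libraries paired by number the exact sign-flip p was 0.125, the smallest 4 pairs allow. With 1 library left out, the exact p was 0.0571 without GFP high replicate 4 (-3.95 points) and without GFP low replicate 1 (-5.08), replicate 3 (-6.22) or replicate 4 (-5.17). Of the thinned cells, 3352 of 9278 in GFP high and 2164 of 7222 in GFP low held 3 or 4 cycle UMIs, next to the threshold, so the call marks a range and not a cell type. The median cell held 3 cycle UMIs in GFP high and 4 in GFP low, so the share at 4 UMIs is no count of dividing cells. The proliferating clusters 6 and 9, described below, held 348 and 108 GFP high cells and 757 and 488 GFP low cells. Free RNA in the droplets also adds cycle UMIs to cells that do not divide, and its amount in each fraction was not measured.

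**Figure D1:**
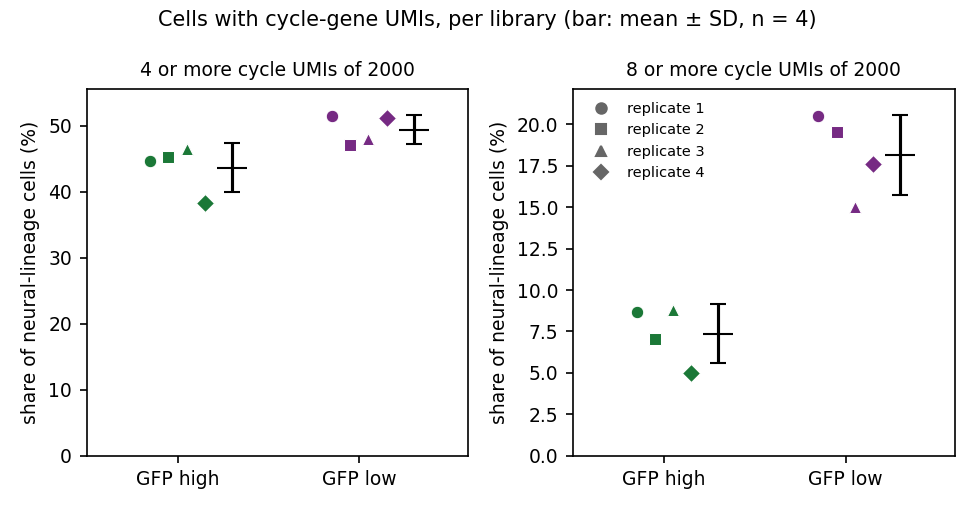
Share of neural-lineage cells (%) with at least 4 or at least 8 UMIs of cell-cycle genes among 2000 UMIs per cell; each point is 1 library, bars are means and error bars SD of 4 libraries per fraction. The GFP high libraries lie below all GFP low libraries at both thresholds, at 43.7 against 49.4% and 7.37 against 18.2%.

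The main comparison set the summed RNA of neural-lineage cells of GFP high against that of GFP low. Synpr, a synaptic vesicle membrane protein, was at 46.6 ± 14.5 CPM in GFP high and 8.92 ± 3.46 in GFP low, a log2 difference of 2.47 ± 0.27 (SE; adjusted p = 0.000303). Hpgd, the enzyme that inactivates prostaglandins, was at 164 ± 58.8 against 29.5 ± 6.79 CPM (log2 2.46, adjusted p = 0.000172). Opalin, a membrane protein of oligodendrocytes, was at 60.3 ± 19.1 against 11.8 ± 3.68 CPM (adjusted p = 3e-04), and Nkx6-2, a transcription factor of the same lineage, was 1.99 higher on the log2 scale. Myl9, a myosin regulatory light chain, rose by 2.41, the retinaldehyde dehydrogenase Aldh1a1 by 2.31 and the insulin-like growth factor binding protein Igfbp7 by 2.37. Evi2a was at 23.9 against 6.06 CPM. Synpr, Myl9, Hpgd and Opalin are among the leading genes of cluster 2, described below. That cluster held 2400 GFP high and 290 GFP low cells. Aldh1a1 leads cluster 0, which held 2958 GFP high and 929 GFP low cells. Summed RNA also changes with the mix of clusters, so that mix stays open as a source of part of these rises.

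Sox9, a transcription factor of neural stem cells and astrocytes, had the largest decrease among the genes that met the naming rule. It fell from 35.6 ± 14.5 CPM in GFP low to 3.34 ± 1.24 CPM in GFP high, 10.8-fold (log2 -3.43 ± 0.307 SE, adjusted p = 0.000127, edgeR). Prps1, which makes the phosphoribosyl pyrophosphate used for nucleotide synthesis, fell by 2.16 on the log2 scale (5.03 ± 1.09 against 22.3 ± 2.17 CPM, adjusted p = 4.16e-05). The RNA-binding protein gene Igf2bp2 was at 8.11 ± 3.73 against 30.5 ± 10.0 CPM (adjusted p = 0.00107), and the extracellular glutathione peroxidase gene Gpx3 at 14.4 ± 3.79 against 53.9 ± 14.9 CPM (adjusted p = 0.000377). The other genes of the 8 largest decreases were Knstrn (-1.71), Ccnb2 (-1.64) and Cenpw (-1.59), which act in mitosis, and the non-coding Lockd (-1.61). Sox9 and Gpx3 are among the leading genes of cluster 7, which held 524 GFP high and 3023 GFP low cells. Sox9 was also lower within the astrocyte-like class (2.90 against 9.36 CPM, log2 -1.73, edgeR adjusted p = 0.0117). It was lower in the proliferating class too (9.56 against 45.8 CPM, log2 -2.32, 0.017). That call was lost with DESeq2 (0.0908) and without GFP high replicate 3 (0.0624) or 4 (0.0922). The mix of these classes with others does not give a fall within them, although free RNA from cluster 7 stays open there. The mix of clusters stays open for part of the fall of Sox9 and Gpx3.

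In all, 1726 of the 13628 genes tested were higher in GFP high and 1636 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted, 5084 at an unadjusted p under the threshold). The fractions did not overlap for 3617 genes, 26.5% of those tested, where chance gives 2.86%. Drawing 300 cells per library lowered the count of genes past the threshold to 2062. In the GENCODE vM21 annotation of the mouse genome GRCm38, matched by Ensembl ID, Sox9 (ENSMUSG00000000567) lies on chromosome 11 at 112782224 to 112787760, Gpx3 (ENSMUSG00000018339) on chromosome 11 at 54902453 to 54910377, Hpgd (ENSMUSG00000031613) on chromosome 8 at 56294585 to 56321043 and Synpr (ENSMUSG00000056296) on chromosome 14 at 13284780 to 13616340, all on the plus strand. Igf2bp2 (ENSMUSG00000033581) lies on the minus strand of chromosome 16 at 22059009 to 22163299.

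**Figure D2:**
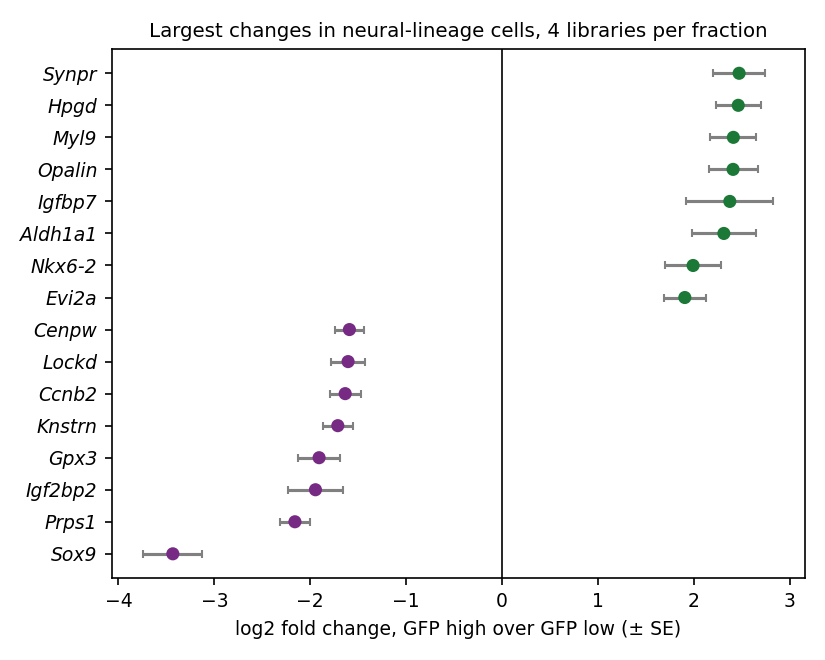
Log2 fold change of GFP high over GFP low in neural-lineage cells (horizontal axis) for the 8 increases and 8 decreases with the largest change; points are edgeR estimates and bars are standard errors, from 4 libraries per fraction. Synpr is 2.47 higher and Sox9 3.43 lower on the log2 scale, a change written -3.43 in the text.

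Genes of the cell cycle were lower in GFP high. Of 41 G1/S genes, which act in DNA replication, 33 fell and the other 8 did not pass (36 adjusted over the list alone), with a median log2 difference of -0.87. They included Nasp (-0.54), a histone chaperone, Rrm1 (-0.48), a subunit of ribonucleotide reductase, and Tipin (-0.59), which travels with the replication fork. Of 52 G2/M genes, which act in mitosis, 46 fell and 6 did not pass (47 adjusted over the list alone). The proliferation marker Mki67 was at 37.5 ± 12.1 against 98.0 ± 22.0 CPM (log2 -1.40, adjusted p = 0.00207), Top2a, the topoisomerase of dividing cells, was 2.29-fold lower (adjusted p = 0.00843), and Hmgb2 was at 108 against 284 CPM. Of 22 chromatin and histone genes, 12 fell and 10 did not pass (13 adjusted over the list alone, median -0.78), among them the histone variant H2afz (-0.69) and the nucleosome-binding Hmgn2 (-0.84). Histone genes have near-identical copies, so single members are uncertain, and without GFP high replicate 2 only 7 of these 22 passed.

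The cell cycle inhibitors, which hold cells in G1 or out of the cycle, did not move together. Of 18 inhibitors and pocket proteins 4 were higher, 1 was lower and 13 did not pass, with a median of 0.13 (camera adjusted p = 0.531). Cdkn1a (p21), Cdkn1b (p27) and Cdkn1c (p57) had log2 differences of 0.64 (adjusted p = 0.271), -0.14 (0.279) and 0.37 (0.221), and Cdkn2a one of -0.31 (0.0945). Cdkn1a passed without GFP high replicate 4 (0.00658, range 0.00658 to 0.658 over its alternatives) and Cdkn1c without GFP low replicate 1 (0.0103) or with the replicate block (0.0321, range 0.0103 to 0.433). Cdkn2a passed without GFP low replicate 2 (0.0377), with DESeq2 (0.047) or with the block (0.02, range 0.02 to 0.257). Ndrg2 rose by 0.45 (adjusted p = 0.00807).

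Genes of the protein-making machinery were lower in GFP high. Of 69 genes of cytosolic ribosomal proteins, 68 fell in GFP high and 1 did not pass (69 adjusted over the list alone), with a median log2 difference of -0.69. Rpl23 was at 2053 ± 139 CPM in GFP high and 3396 ± 317 in GFP low (log2 -0.73, adjusted p = 0.00111) and Rpsa fell by 0.62. Ribosomal protein genes have many processed pseudogenes, so the split of UMIs between copies is uncertain for single members. Of 30 ribosome biogenesis genes 25 fell and 5 did not pass (29 adjusted over the list alone, median -0.54). These included the nucleolar proteins Npm1 (751 ± 83.5 against 1324 ± 174 CPM, adjusted p = 0.00122) and Ncl (-0.62) and the small nucleolar ribonucleoprotein Nop10 (-0.68).

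Of 19 genes linked to activation of neural stem cells and held outside the cycle lists, 10 fell, 1 rose and 8 did not pass (11 and 1 adjusted over the list alone, median -0.31). The 10 were Nes, an intermediate filament of neural progenitors, Myc, Cdk4 and Eif1a, the ribosomal Rpl32 (-0.86) and Rpl41 (-0.69), and the nucleolar Npm1, Fbl, Ncl and Nop56, so 6 of the 10 are genes of ribosomes or the nucleolus. The 1 increase was lost without GFP high replicate 2 or 3 or GFP low replicate 1. Of 49 genes of oxidative phosphorylation 7 fell and 42 did not pass, with a median of -0.14. Cox6a1, a subunit of cytochrome c oxidase, was at 413 against 528 CPM (log2 -0.35, adjusted p = 0.0129). Adjusted over the list alone the count was 0, although 16 had an unadjusted p under the threshold and DESeq2 called 15 over all genes. The 7 became 1 without GFP high replicate 1, 2 or 3, 2 without GFP low replicate 2 or 4, 16 without GFP high replicate 4 and 14 with the replicate block.

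Part of the genes of glial states were higher in GFP high. Of 23 genes of myelin and mature oligodendrocytes, 16 rose and 7 did not pass (19 adjusted over the list alone, median 0.88). The deacetylase gene Sirt2 was at 1446 ± 234 against 674 ± 92.7 CPM, and Cnp rose by 0.73. Of 30 genes of the oligodendrocyte-progenitor-like (OPC-like) state of glioblastoma, 18 rose, 1 fell and 11 did not pass (20 and 2 adjusted over the list alone, median 0.46), with Tmem176b at 0.58. The 1 decrease was lost without GFP high replicate 2, 3 or 4 or GFP low replicate 1 or 4, and there were 2 with the replicate block. Of 29 genes of the astrocyte-like (AC-like) state, 16 rose, 2 fell and 11 did not pass (17 and 2 adjusted over the list alone, median 0.45). The calcium-binding protein gene S100b was at 796 against 510 CPM, the brain proteoglycan Bcan rose by 0.49 and Cpe, a carboxypeptidase, by 0.56. The 2 decreases were lost without GFP high replicate 1 or GFP low replicate 2, and 1 of them without GFP high replicate 3 or GFP low replicate 3.

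Of 35 genes of quiescent neural stem cells and astrocytes, 15 rose, 3 fell and 17 did not pass (15 and 3 adjusted over the list alone, median 0.34). Apoe, the main lipid carrier of the brain, had the largest rise among the members named, from 309 ± 54.3 to 914 ± 245 CPM (log2 1.56, adjusted p = 0.000426), and Gpr37l1, an astrocyte receptor, rose by 0.49. The 3 that fell were the transcription regulators Sox9, Hes1 and Hopx, which are themselves associated with stem cells and astrocytes, and there were 5 decreases without GFP low replicate 1. This list's call was lost without GFP high replicate 2 (camera adjusted p = 0.125), GFP high replicate 4 (0.0583) or GFP low replicate 1 (0.257), with fry, which tests a list against no change and not against other genes (0.0591), and in non-cycling cells (0.191, or 0.0539 for cells of fewer than 8 cycle UMIs). It was also lost with an estimated correlation between genes (0.642, or 0.656 with the replicate block). The adjusted p ranged from 0.00697 to 0.656 over its alternatives. Gfap, the astrocyte intermediate filament, was at 106 ± 65.6 against 46.1 ± 11.6 CPM (log2 1.19, edgeR adjusted p = 0.0238), with 202.9 CPM in GFP high replicate 4, and missed the threshold without GFP low replicate 3 (0.0512) and with 300 cells per library (0.123). Olig2, which marks the oligodendrocyte lineage, differed by 0.18 (adjusted p = 0.177), and the mesenchymal marker Cd44 by -0.06 (0.908). Egfr had too few counts to be tested.

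Part of the interferon response and lysosome genes were also higher in GFP high. Of 28 interferon response genes, 13 rose and 15 did not pass (14 adjusted over the list alone, median 0.41), and with the replicate block 20 rose. The library means of this list overlapped, and its camera call (adjusted p = 2.74e-07) was lost with an estimated correlation (0.556) and missed with fry (0.0586, range 6.56e-12 to 0.556). Iigp1, an interferon-induced GTPase, was at 933 ± 225 against 514 ± 157 CPM (log2 0.86, adjusted p = 0.016). Ifit3 was 2.65-fold higher (562 ± 118 against 212 ± 43.1 CPM), with the reservation that its UMIs can be shared with the near-identical Ifit3b. Of 24 genes of lysosomes and autophagy, 12 rose, 1 fell and 11 did not pass (14 and 1 adjusted over the list alone, median 0.38; camera adjusted p = 3.18e-06, lost with an estimated correlation, 0.466, range 4.69e-08 to 0.466), with the lysosomal membrane protein Lamp1 at 618 against 418 CPM, Psap at 0.63 and Laptm4a at 0.48. Of 18 antigen presentation genes 2 were higher and 16 did not pass, with 1 adjusted over the list alone (median 0.29, camera adjusted p = 0.0599). This list passed without GFP high replicate 2 (0.0354), GFP high replicate 3 (0.00642), GFP low replicate 1 (0.035) or GFP low replicate 4 (0.00122) and with the replicate block (5.21e-05), in a range of 5.21e-05 to 0.895 over its alternatives. With an estimated correlation between genes it did not pass, without the block (0.895) or with it (0.347). Its class I genes H2-K1 (0.31, adjusted p = 0.144; 0.0352 with the block, range 0.0352 to 0.323) and B2m (0.01, 0.971) did not pass, and H2 genes share near-identical sequence.

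The lists were compared with all other genes by limma's camera, with a preset correlation of 0.01 between genes and adjustment over 32 lists, and 13 passed. The adjusted p was 1.38e-20 for G1/S, 2.69e-31 for G2/M, 2.69e-08 for chromatin and histones, 1.32e-44 for ribosomal proteins, 2.85e-16 for ribosome biogenesis, 1.65e-05 for activated stem cell genes and 0.000874 for oxidative phosphorylation, all lower in GFP high. It was 1.19e-10 for myelin, 9.4e-09 for OPC-like, 7.53e-05 for AC-like, 0.0122 for quiescent stem cell and astrocyte genes, 2.74e-07 for interferon response and 3.18e-06 for lysosome genes, all higher. With the correlation between genes estimated from the 8 libraries, none of the 13 calls held, while fry, whose question is only whether a list changed, called 10 of them. In the same order, adjusted p = 0.293, 0.293, 0.405, 0.24, 0.24, 0.24 and 0.888 with an estimated correlation for the lists that were lower, and adjusted p = 0.293, 0.24, 0.461, 0.642, 0.556 and 0.466 with an estimated correlation for those that were higher. The library means of all 4 GFP high libraries lay on one side of all 4 GFP low libraries for 10 of the 13, the exceptions being oxidative phosphorylation, quiescent stem cell and interferon genes. The test fry left out oxidative phosphorylation (adjusted p = 0.141, range 3.39e-07 to 0.888), interferon response (0.0586, range 6.56e-12 to 0.556) and the quiescent list.

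**Figure D3:**
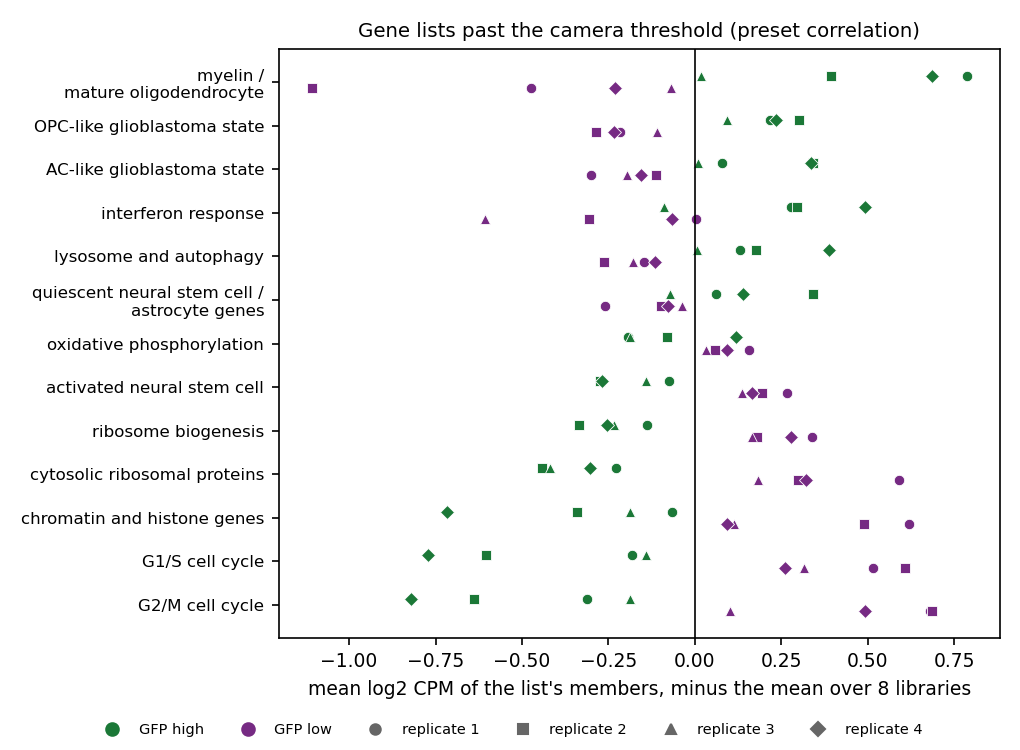
Mean log2 CPM of each list's genes in each library, minus the mean over the 8 libraries, for the 13 gene lists past the camera threshold in neural-lineage cells; each point is 1 library of GFP high or GFP low. The fractions separate fully for 10 lists, including ribosomal proteins with a median gene difference of -0.69 and myelin genes with 0.88.

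The remaining lists did not pass, and all of them but the antigen presentation and the BMP and TGF-beta lists had calls in both directions. In metabolism and oxygen sensing, 3 of 26 hypoxia genes were higher and 3 lower (median 0.09, camera adjusted p = 0.646), with the lactate dehydrogenase gene Ldha lower by a log2 difference of -0.62 (edgeR adjusted p = 0.0116) and Aldoa at 0.18 (0.366). Glycolysis had 2 higher and 3 lower of 20, a median of 0.04, a mean of -0.02 and a test direction of lower (0.945), with Gapdh at 0.01 and Pkm at -0.07. Cholesterol synthesis had 1 higher and 1 lower of 24 (median -0.05, 0.73), with Hmgcs1 at 0.12 and Fdps at -0.16. Fatty acid oxidation and lipid droplets had 4 higher and 3 lower of 20 (median 0.09, 0.602).

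Among tumour states, 7 of 30 genes of the neural-progenitor-like state were higher and 5 lower, with a median of 0.16 and a mean of -0.05 (camera adjusted p = 0.619). The growth cone gene Gap43 rose by 0.68 (edgeR adjusted p = 0.00434) while Tubb2b differed by 0.16 (0.438). The mesenchymal-like state had 6 higher and 5 lower of 28 (median 0.23, 0.803), with S100a6 at 0.48 (edgeR adjusted p = 0.0637) and Ifitm3 at 0.21 (0.543). S100a6 passed with the replicate block (0.0427), DESeq2 (0.0237) or 300 cells per library (0.0221, range 0.0221 to 0.143 over its alternatives). The stress lists did not pass either. Immediate early genes had 3 higher and 5 lower of 25 (median -0.02, mean 0.00, camera 0.803) with Jun at 0.43 and Jund at 0.36, neither of which passed. Jun passed with the replicate block (edgeR adjusted p = 0.00152) or without GFP low replicate 4 (0.0392, range 0.00152 to 0.378), and Jund with the block (0.00691) or sex as a covariate (0.0171, range 0.00691 to 0.257). Heat shock genes had 1 higher and 3 lower of 15 (median -0.12, 0.436) with Hsp90ab1 at -0.27 and Hspa8 at -0.12. Unfolded protein response genes had 3 higher and 5 lower of 25 (median -0.18, 0.426), with the chaperone Calr lower at -0.45 (edgeR adjusted p = 0.0139) and Hspa5 at -0.34 (0.0768). Hspa5 passed with the block (0.01), DESeq2 (0.0302) or without GFP low replicate 3 (0.0145, range 0.01 to 0.192). Targets of p53 had 2 higher and 2 lower of 18 (median 0.12, 0.803), with Rps27l lower at -0.64 (0.00117) and Bax at -0.09 (0.585).

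Signalling and matrix lists did not pass either. The Notch list had 3 higher and 2 lower of 16 (median -0.07, camera adjusted p = 0.939), with Dner at 0.62 (edgeR adjusted p = 0.00265) and Notch1 at -0.09 (0.496). The BMP and TGF-beta list had 4 higher of 17 and the other 13 did not pass (median 0.10, 0.191), with the ligand Bmp4 at 0.74 (0.0063) and Id2 at -0.23 (0.41). The Wnt list had 3 higher and 2 lower of 15 (median 0.21, 0.803), with Ccnd1 at -0.25 and Tcf7l2 at 0.21 (0.142; 0.0479 without GFP high replicate 2, range 0.0479 to 0.326). Growth factor signalling targets had 1 higher and 2 lower of 19 (median -0.14, 0.275), with the receptor Pdgfra at -0.10. Extracellular matrix had 5 higher and 3 lower of 25 (median 0.28, 0.646), with the perineuronal net protein Tnr at 0.75 (0.00125). Adhesion and niche receptors had 3 higher and 2 lower of 14, a median of -0.06 and a test direction of higher (0.803), with Ncam1 at 0.43 (0.00447). Cilium genes had 1 higher and 2 lower of 7 (median -0.05, 0.856), with the axonemal dynein Dnah5 at 0.84 (0.0144), which missed the threshold with 300 cells per library. Of the 19 lists that did not pass, antigen presentation included, 14 had a count of higher or lower members that moved by over 1.5 times when 1 library was left out, and each of the 8 libraries did so for at least 1 list. With the replicate block, 12 neural-progenitor-like, 10 mesenchymal-like, 8 hypoxia, 5 glycolysis, 9 immediate early and 10 antigen presentation genes were higher, and 9 unfolded protein response, 7 matrix and 5 growth factor signalling genes were lower. Counts of 1 became 2 with the block for inhibitors and cholesterol genes lower and for heat shock, cholesterol and cilium genes higher.

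With every cell kept, immune cells included, 1674 genes were higher and 1602 lower of 13706 tested (edgeR, 5060 at an unadjusted p under the threshold). Of these, 3243 were also called in neural-lineage cells alone, and the fold changes of the 2 fits correlated across genes at r = 0.991, which describes overlapping cells and is no independent check. Synpr (2.48), Hpgd (2.46), Sox9 (-3.43) and Igf2bp2 (-1.94) kept their places among the largest changes.

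The next question was whether the fractions differed outside cycling cells. Among neural-lineage cells below the cycling threshold, 1025 genes were higher in GFP high and 877 lower of 12685 tested (edgeR, 3755 at an unadjusted p under the threshold), and 1810 of them were also called in all neural-lineage cells. Igfbp7 rose by 2.85, Synpr by 2.44 and Myl9 by 2.42 on the log2 scale. Sox9 was at 2.86 ± 0.721 CPM in GFP high and 28.6 ± 2.21 in GFP low (log2 -3.36, adjusted p = 4.67e-07), and Igf2bp2 fell by 2.13. The ribosomal protein genes fell in these cells too, with 68 of 69 lower and a median of -0.72. Interferon genes kept a median of 0.44, with 12 of 28 higher, 7 without GFP high replicate 2 and 6 without GFP high replicate 4 (19 with the replicate block). Myelin genes had a median of 0.50, with 6 of 23 higher, 10 without GFP high replicate 3 and 13 with the block, and lysosome genes had 9 higher and 1 lower of 24. Of 37 G2/M genes that could still be tested 13 fell. At a threshold of 2 UMIs 4 of 22 tested fell, and at 8 UMIs 21 of 43 fell and 1 rose. The fractions did not overlap for 2478 genes, 19.5% of those tested against 2.86% by chance. At a threshold of 2 cycle UMIs the count of genes past the threshold was 1165, and without GFP high replicate 2 it was 1187.

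Within classes of cells, 11 clusters were found. Clusters 0 and 1 were astrocyte-like by their markers, although they also held Olig2 and Pdgfra, genes of the oligodendrocyte lineage. Each had 1 such marker among its first 10 genes. With the strict cell filter, or with every deposited barcode, no cluster took this name. Olig2 was at 818 and 839 CPM in them and at 277 CPM in the immune cluster, which should lack it, and Pdgfra was at 555 and 771 CPM against 173. Tdtomato RNA was also present in the immune cluster, at 1069 CPM, so values within a class can include RNA of other cells. Clusters 3 and 4 were mature-oligodendrocyte-like, 6 and 9 were proliferating, 10 held immune cells, and 2, 5, 7 and 8 stay unnamed. Cluster 2 was led by Synpr, Serpina3n and Apol6, cluster 5 by Gpc5, Malat1 and Chgb with few UMIs per cell, cluster 7 by Pnlip, Rasl11a and Gpx3, and cluster 8 by Fxyd1, Igfbp5 and Art3. Cluster 6 held most of the proliferating cells in each library. Of the astrocyte-like cells, cluster 0 held more than cluster 1 in GFP high replicate 4 (2022 against 89) and in GFP low replicates 1 (86 against 79) and 4 (773 against 97), and cluster 1 held more in the other 5 libraries.

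In the mature-oligodendrocyte-like class, 666 genes were higher and 587 lower in GFP high of 10661 tested (edgeR, 2697 at an unadjusted p under the threshold). Chst8, a sulfotransferase, was at 55.3 ± 18.4 against 7.78 ± 3.47 CPM (log2 2.78, adjusted p = 0.000253), the urea transporter gene Slc14a1 rose by 2.51 and Hpgd was at 499 against 97.3 CPM. Pnlip, which also leads cluster 7, was at 2.25 against 24.1 CPM, Cbln2 fell by 2.77, and Gpx3, another of that cluster's leading genes, was at 7.50 against 45.7 CPM (log2 -2.54, adjusted p = 0.000249). The ribosomal protein genes had a median of -0.92 here, the lowest of the 7 classes tested. Of 49 oxidative phosphorylation genes 21 fell (30 adjusted over the list alone, median -0.33), 11 of 24 lysosome genes rose (median 0.50) and 8 of 28 interferon genes rose (median 0.57). Cluster 4 held 892 of the GFP high and 530 of the GFP low cells of this class, and cluster 3 the other 69 and 171. The count of 1253 genes became 603 without GFP low replicate 1, 659 without GFP high replicate 2 and 791 without GFP high replicate 4.

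Fewer genes passed in the other classes. In the astrocyte-like class 19 were higher and 18 lower of 11768 (976 at an unadjusted p under the threshold). Hmga2, a chromatin protein of growing and embryonic tissue, was at 8.24 ± 1.46 against 21.8 ± 2.84 CPM (log2 -1.38, adjusted p = 0.00428). Hmga2 was at 79.1 CPM in cluster 7, which held 524 GFP high and 3023 GFP low cells. Free RNA or stray cells of that cluster therefore stay open for this fall. The count of 37 became 11 without GFP high replicate 1, 23 without GFP low replicate 1, 9 without GFP low replicate 2, 14 without GFP low replicate 4 and 224 with the replicate block. In cluster 2, 73 were higher and 110 lower of 10875 (1532 unadjusted). The ligand Bmp4 was at 62.0 against 20.9 CPM (log2 1.69, adjusted p = 0.000757), Nkx6-2 rose by 1.44, Myl9 was 3.59-fold higher, and Igf2bp2 was at 6.40 against 29.8 CPM (log2 -2.48). Its count of 183 became 63, 93 and 57 without GFP high replicate 2, 3 or 4, and 39 and 107 without GFP low replicate 1 or 4.

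In cluster 7, 20 genes were higher and 6 lower of 10774 (1133 unadjusted). Apoe was at 485 ± 88.2 against 214 ± 12.9 CPM (adjusted p = 0.000679), the actin-binding calponin Cnn2 at 156 against 68.0 CPM, and Plvap rose by 1.14. Its count of 26 became 10 without GFP high replicate 2, 15 without GFP high replicate 4, 13 without GFP low replicate 2 and 274 with the block. In the proliferating class 108 were higher and 36 lower of 10344 (1493 unadjusted). Ly6a rose by 2.65 (22.7 against 2.91 CPM, adjusted p = 0.00124), Synpr by 2.25 and Hpgd by 2.14, and Ptgds, which makes prostaglandin D, was at 139 against 41.3 CPM. Igfbp2 fell by 2.80 and the mitochondrial creatine kinase gene Ckmt1 by 1.44. The count of 144 became 73 without GFP high replicate 3, 95 without GFP high replicate 4 and 553 with the block.

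Cluster 5 could be tested in 3 libraries per fraction, with 26 genes higher and 47 lower of 5861 (643 unadjusted). These were GFP high replicates 1, 2 and 3 and GFP low replicates 1, 3 and 4. Sex was therefore not balanced between the fractions, and replicates 2 and 4 had no partner. The cells of this cluster held a median of 11.5% mitochondrial UMIs, where no other cluster exceeded 5.68%. Gpnmb, a glycoprotein of lysosomes and melanosomes, was at 515 ± 51.2 against 165 ± 35.5 CPM (log2 1.53, adjusted p = 9.19e-05), and Igfbp2 (-2.71) and Moxd1 (-2.76) were lower. The count of 73 became 6 and 8 without GFP high replicate 1 or 2, 1 and 43 without GFP low replicate 1 or 4, and 22 with the block. Cluster 8, with 4 against 3 libraries, gave 0 genes with edgeR, although 918 of 7896 had an unadjusted p under the threshold and DESeq2 called 79, edgeR with no filter 167 and with the replicate block 6. Leaving out GFP low replicate 1 gave 7 genes and leaving out GFP high replicate 2 gave 1. In this cluster 27 of 28 interferon genes were higher in GFP high without a single call over all genes, with a median of 0.74 and 8 past the threshold adjusted over the list alone. A difference in the number of calls between classes was not tested, and the classes differ in cell number.

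The ribosomal protein genes had a median below 0 in each of the 7 classes tested, and single members passed in 4 of them. At least 68 of the 69 members were below 0 in every class, with medians of -0.30 in the astrocyte-like class, -0.43, -0.75, -0.23 and -0.37 in clusters 2, 5, 7 and 8, -0.92 in the mature-oligodendrocyte-like class and -0.34 in the proliferating class. In the 5 classes with 4 libraries per fraction, the mean of the list was lower in all GFP high libraries than in any GFP low library (exact permutation p = 0.0286 in each, the smallest possible). This relabelling ignores the pairing of the libraries, and the smallest exact sign-flip p that 4 pairs allow is 0.125. In cluster 5, with 3 against 3, the exact p was 0.1, again the smallest possible. Over all genes, 69 of the 69 members passed in the mature-oligodendrocyte-like class, with each library left out too, 23 in cluster 5, 11 in cluster 2 and 4 in the proliferating class. With edgeR 0 of the 69 passed in the astrocyte-like class, cluster 7 and cluster 8, where 54, 36 and 41 had an unadjusted p under the threshold, 48, 17 and 30 passed adjusted over the list alone and DESeq2 called 20, 11 and 1. The list does not hold every ribosomal protein gene. Rpl23a, outside it, was lower in the astrocyte-like class (log2 -0.52, edgeR adjusted p = 0.0276) and in the proliferating class (-0.57, 0.0195). DESeq2 called 30 each in clusters 2 and 5 and 20 in the proliferating class, and with no filter on low counts edgeR called 2 in the astrocyte-like class, 21, 12, 4 and 0 in clusters 2, 5, 7 and 8 and 15 in the proliferating class. The replicate block gave 21 in the astrocyte-like class, 34, 5, 9 and 0 in clusters 2, 5, 7 and 8 and 42 in the proliferating class. Leaving out GFP high replicate 1, 2, 3 or 4 gave 0, 2 and 9 in cluster 5 for the first 3 of these, 2, 4 and 7 in cluster 2 for the last 3, and 8, 1, 1 and 2 in the proliferating class. Leaving out GFP low replicate 1 or 4 gave 5 and 7 in cluster 2, leaving out replicate 1, 3 or 4 gave 0, 47 and 11 in cluster 5, and leaving out replicate 2 or 3 gave 1 each in the proliferating class. At the 0 counts of cluster 5, 54 and 27 members had an unadjusted p under the threshold. The astrocyte-like class gave 4 without GFP high replicate 4, and cluster 7 gave 1 without GFP low replicate 1.

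**Figure D4:**
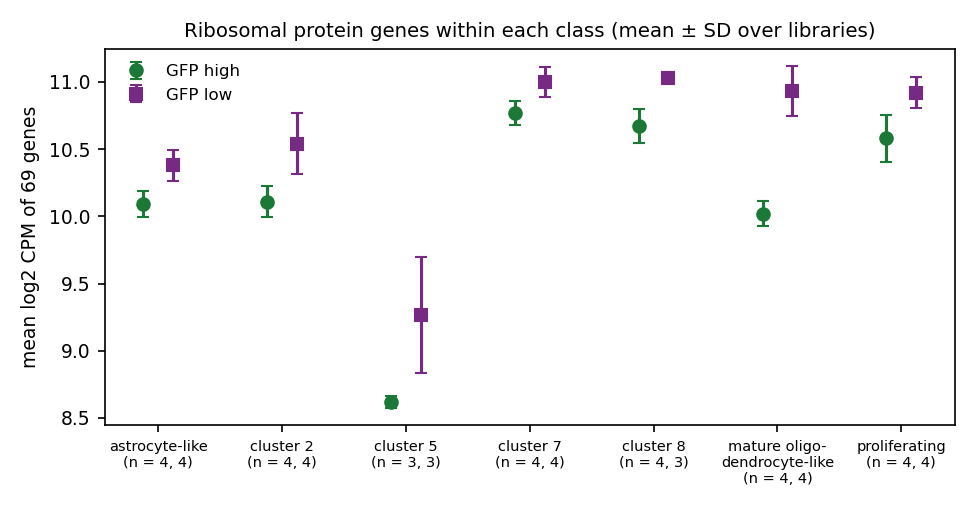
Mean log2 CPM of 69 cytosolic ribosomal protein genes in the 7 classes of neural-lineage cells. Each point is the mean over the libraries of GFP high or GFP low, and bars show the SD. There were 4 libraries per fraction, except for 3 and 3 in cluster 5 and 4 and 3 in cluster 8. GFP high lies lower in each class, with gene medians from -0.92 in the mature-oligodendrocyte-like class to -0.23 in cluster 7.

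Whether the effect of the fraction differed between classes or sexes was tested directly. Between the astrocyte-like class and cluster 7, the pair of classes with the most cells, the effect differed for 5 of 11495 genes (edgeR interaction, 751 at an unadjusted p under the threshold, 42 past it with no filter). Hmga2 fell in the astrocyte-like class (-1.38) and not in cluster 7 (-0.15; adjusted p of the difference = 0.000404), and Apoe rose more in cluster 7 (1.18 against 0.51; 0.00668). H19, an imprinted non-coding RNA, had log2 differences of 0.21 and -1.43 (0.0109), Rtn1 of 0.03 and 0.45 (0.00668), and Lims2 of 0.32 and -0.16 (0.042). Hmga2 passed with each library left out in turn. It is among the leading genes of cluster 7, so free RNA from that cluster stays open for its fall in the astrocyte-like class. Apoe and Rtn1 missed the threshold without GFP high replicate 2 (0.0552 for both, ranges 2.89e-09 to 0.0552 and 0.0017 to 0.0552 over their alternatives). H19 missed it without GFP high replicate 2 (0.0575) or 4 (0.0896) or GFP low replicate 3 (0.0509) or 4 (0.133), with a lowest value of 2.35e-19 without a filter. Lims2 passed without GFP high replicate 3 (0.0469) and in no other fit that left out 1 library, where it lay between 0.0659 and 0.12, and with all libraries it was lost with DESeq2 size factors (0.0513). The count of 5 became 1 without GFP high replicate 2, 9 without GFP high replicate 3 and 15 without GFP high replicate 4. For sex by fraction edgeR called 0 genes, with 278 at an unadjusted p under the threshold, 95 past it with no filter, 12 with the replicate block and 1 without GFP high replicate 4. On simulated data with the same libraries this test found 46 of 66 genes changed 4-fold and 13 of 67 changed 2-fold, so smaller differences between sexes were not detectable.

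Immune cells, mostly expressing the microglia and macrophage genes C1qa, C1qb and Ctss, made up 0.758 ± 0.653% of GFP high and 1.64 ± 2.06% of GFP low cells (SD, n = 4; exact permutation p = 0.6). GFP low replicate 3 held 4.62%, and without it the difference of -0.880 points turned to 0.114 (exact p = 0.857). GFP low replicate 2 held 0 immune cells beside 293 neural-lineage cells, which allows a share of up to 1.02%, for counting error only. The tdTomato gate was meant to exclude such cells, so these shares describe the sort. The median UMI count per neural-lineage cell was 9786 ± 510 in GFP high and 15260.0 ± 6028 in GFP low (exact p = 0.0571), and without GFP low replicate 4 the difference of -5475 became -7124 (exact p = 0.0286). Without GFP low replicate 2, the library with 23819 UMIs per cell, it was -2622 (exact p = 0.0571). The GFP low libraries of few barcodes had the most UMIs per cell, with 373 barcodes in replicate 2 and 652 in replicate 3 (15000 UMIs). Replicates 1 and 4, with 3369 and 4055 barcodes, had 11908.5 and 10314. Sequencing depth per cell was not controlled for, so these values do not measure RNA content alone. In 2000 UMIs, GFP high cells showed a median of 1226 ± 15 genes and GFP low cells 1189 ± 23.5 (exact p = 0.0571; with means in place of medians, exact p = 0.0286; without GFP low replicate 3, exact p = 0.0286). In each same-numbered pair the GFP low library had the higher median UMI count and the GFP high library more genes. The smallest exact sign-flip p that 4 pairs allow is 0.125.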

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

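In this part, the tests of the share of cycling cells, of the mix of clusters and of other splits of the libraries, the fit of the larger oligodendrocyte cluster and the interaction tests with 1 library left out were chosen only after the results were seen.

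A single library stood apart from the other 3 of its fraction in 15 of 268 groups of 4 libraries looked at. Chance gives about 1 in 20 groups, here 13.4, so their number is close to what chance gives. In GFP high, the mean of the hypoxia list was 4.38 log2 CPM in replicate 3 and at most 4.18 in the others. Igf2bp2 was at 13.7 CPM in GFP high replicate 1, against at most 6.59. GFP high replicate 4 held S100a6 at 1981.0 CPM, Gapdh at 1646 and the astrocyte filament Gfap at 202.9, where the other libraries reached 1211, 1227 and 83.4, and Notch1 at 71.5 where they held at least 82.3. In GFP low, replicate 2 had the highest Sox9 (57.2 CPM, others at most 30.5), Anp32e (237.0, others at most 194) and Nop10 (257.9, others at most 237.4). GFP low replicate 3 had Gpr37l1 at 618 CPM and Cd44 at 10.2, above 525 and 5.74 in the next library, and Ifit3 at 147 and Tcf7l2 at 72.2, below 231.5 and 81.2. S100b was at 488 CPM in GFP low replicate 1 and at least 515 in the others. Egfr was at 0.531 CPM in GFP low replicate 4 and at most 0.274 in the others, too low to be tested.

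The effect of the fraction differed between the astrocyte-like class and cluster 7 for 5 genes by the edgeR interaction test, given here as the effect in cluster 7 minus that in the astrocyte-like class. The log2 difference was 1.26 for the chromatin protein gene Hmga2, 0.66 for Apoe, 0.42 for Rtn1, -1.74 for H19 and -0.48 for Lims2. For Hmga2, a leading gene of cluster 7, free RNA from that cluster in the astrocyte-like class stays open. Chance cannot be excluded for the number of such genes, since 4 of the 35 splits of the 8 libraries gave at least as many, with 5 for the real split and 8 as the highest other. Without GFP high replicate 2 the count was 1, without GFP high replicate 3 it was 9 and without GFP high replicate 4 it was 15. Chance cannot be excluded for the number of gene lists past the camera threshold either. That number was 13, and 17 of the 35 splits gave at least 13, with 17 as the highest other and 15 as the highest among the splits that part all 4 pairs of same-numbered libraries.

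The first pattern weighed was the lower level of ribosomal protein genes in GFP high, with 68 of 69 lower and a median log2 difference of -0.69. The tables argue against the share of cycling cells, since the median was -0.72 among non-cycling cells, and against the mix of clusters as the whole source, since the list's mean was lower in all GFP high libraries in each of the 5 classes with 4 libraries per fraction. Cells of low RNA quality stay open, since 68 were lower with the strict cell filter but that filter removed at most 3.76% of a library's UMIs and so moved little. Free RNA from other droplets stays open too: the immune cluster held the tumour transgenes Tdtomato at 1069 CPM and EGFRvIII at 4771 CPM, by free RNA, which could reach every class, or by uptake of tumour cells, which would say nothing of the other classes. That slow-cycling cells make less of these mRNAs is therefore 1 of the hypotheses left open. A difference in UMIs per cell, from RNA content or from sequencing depth, may contribute.

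The second pattern was the higher level of interferon response genes in GFP high, with a median of 0.41 in neural-lineage cells. RNA from immune cells is argued against, since the immune gene C1qa was at 3867 CPM in immune cells but at 0.791 in GFP high and 1.37 in GFP low neural-lineage cells, and the interferon genes summed to 8696 CPM in immune cells but to 10730 CPM in GFP high neural-lineage cells. The median of -0.41 over 15 tested markers of microglia and macrophages (quartiles -0.75 and 0.16) adds little, as 9 lay under 2 CPM and calls went both ways. Cd14 (1.07, edgeR adjusted p = 0.0133) and Sparc (0.60, 0.0178) were higher, and C1qb (-1.08, 0.0238) and Olfml3 (-0.54, 0.0474) were lower. The mix of clusters predicts no difference within a cluster, and in the astrocyte-like class and cluster 2 the larger of the 2 list medians was 0.0514, so it stays open there. It stays open too in clusters 5 and 7 and the proliferating class. Their medians were 0.17, 0.10 and 0.12, and their library means overlapped (exact permutation p = 0.8, 0.571 and 0.486). Cluster 2, with Ifit3 and Irf7 among its leading genes, held 2400 GFP high and 290 GFP low cells. In the mature-oligodendrocyte-like class the median of 0.57 argues against it, although the library means overlapped (exact permutation p = 0.114). In cluster 8 the mean was 8.15 against 7.33 log2 CPM (exact permutation p = 0.0286 with the pairing ignored, the smallest possible), and free RNA from other droplets stays open for each class.

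The third pattern was the number of genes that differed within the mature-oligodendrocyte-like class, 1253, where the highest other of the 35 splits of the libraries gave 6. The other 7 splits that part all 4 pairs of same-numbered libraries called no gene. These 8 alone are too few for a share under 0.05, so the splits do not exclude chance once the libraries are taken as paired. Different shares of its 2 clusters are argued against, since the larger cluster alone, with as few as 17 cells in a library, gave 1316 genes, of which 1081 were among the 1253 and 0 went the opposite way. The size of the count depends on single libraries, since it was 603 without GFP low replicate 1, 659 without GFP high replicate 2 and 791 without GFP high replicate 4. Free RNA stays open for part of the genes, since Pnlip and Gpx3, which lead cluster 7, were among the largest decreases in this class. A biological difference between the sorted cells of this class stays among the open explanations, as untested.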

How the results depend on the processing

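Chosen only after the results were seen were the fits without vascular-marker cells or cluster 5, lists below 8 cycle UMIs, the block with an estimated correlation, the larger oligodendrocyte cluster (1316 genes), the interaction tests with 1 library left out and the tests of other splits. Among the summary values under settings that kept all libraries, 56 kept their direction and side of the threshold or a count within 1.5 times, 22 counts moved further, 3 calls were lost and 1 was gained. With 1 library left out 98 were kept, 28 moved, 4 calls were lost, 2 were gained and 1 value turned direction. In neural-lineage cells the count of 3362 genes lay between 2357 (without GFP high replicate 2) and 4201 (replicate block), except for 2062 with 300 cells per library, a setting that has fewer UMIs. Of 130 calls for named genes, 26 were lost without some library, 9 under some other setting, and 0 turned direction. Elsewhere the cause of a change was not tested. With the DESeq2 Wald test the counts were 92 in the astrocyte-like class (37 with edgeR), 46 in cluster 5 (73), 123 in cluster 7 (26), 79 in cluster 8 (0 with edgeR, 918 at an unadjusted p under the threshold) and 227 in the proliferating class (144). With no filter on low counts they were 174 (astrocyte-like), 576 (cluster 2, 183 with the filter), 235 (cluster 7), 167 (cluster 8), 516 (proliferating), 42 for the class interaction (5) and 95 for the sex interaction (0 with edgeR, TMM or RLE, 278 unadjusted with TMM). With the replicate block they were 224 (astrocyte-like), 22 (cluster 5), 274 (cluster 7), 6 (cluster 8), 553 (proliferating) and 12 (sex interaction); the difference in cycling share stayed at -5.76 points with an exact sign-flip p of 0.125, the smallest possible. Beside these and the calls for lists and genes given with the block, the pairing changed no other call of the named results except Dnah11 (gained) and Sdk2 and Pcp4 in cluster 5 (lost). The exact tests of the cycling share at 8 UMIs and of list means within classes were not run with pairs. Non-cycling cells gave 1165 genes at a threshold of 2 cycle UMIs (1902 at 4), and the cycling share differed by -0.174 points at 2 UMIs and by -0.203 unthinned. Genes per 2000 UMIs differed by 40.0 with means. With an estimated correlation 0 lists passed camera, with or without the block, where fry called 10 and the preset correlation 13. With 1 library left out, the non-cycling count was 1187 (without GFP high replicate 2) to 1993. The astrocyte-like count was 9 to 45, with 11 without GFP high replicate 1 and 23, 9 and 14 without GFP low replicates 1, 2 and 4. Cluster 2 gave 39 to 245, with 63, 93 and 57 without GFP high replicates 2, 3 and 4 and 39 and 107 without GFP low replicates 1 and 4. Cluster 5 gave 1 to 107, with 6 and 8 without GFP high replicates 1 and 2 and 1 and 43 without GFP low replicates 1 and 4. Cluster 7 gave 10 to 35, with 10 and 15 without GFP high replicates 2 and 4 and 13 without GFP low replicate 2. Cluster 8 gave 0 to 7, with 1 without GFP high replicate 2 and 7 without GFP low replicate 1. The oligodendrocyte-like class gave 603 to 1282, with 603 without GFP low replicate 1 and 659 and 791 without GFP high replicates 2 and 4, and the proliferating class 73 to 182, with 73 and 95 without GFP high replicates 3 and 4. The class interaction gave 1 to 15 (1, 9 and 15 without GFP high replicates 2, 3 and 4) and the sex interaction 0 to 1 (1 without GFP high replicate 4). The cycling share differed by -6.68 to -3.95 points, and the call was lost without GFP high replicate 4 (-3.95) or GFP low replicate 1 (-5.08), 3 (-6.22) or 4 (-5.17). The immune share went from -1.43 to 0.114 points (the last without GFP low replicate 3), the UMIs per cell from -7124 (without GFP low replicate 4, now past the threshold) to -2622 (without GFP low replicate 2), and the genes per 2000 UMIs from 26.3 to 44.3 (the last without GFP low replicate 3, now past the threshold). Over all 35 splits of the libraries, no other split reached the 3276 genes of the fit with every cell or the 3362 of neural-lineage cells (highest other 8 in each). The same held for 1902 in non-cycling cells (6), 37 in the astrocyte-like class (11), 183 in cluster 2 (8), 26 in cluster 7 (8) and 144 in the proliferating class (6). In each of these the highest other is the split by sex, which parts no pair of same-numbered libraries. The other 7 splits that part all 4 pairs as the real one does called no gene. Only these 8 splits keep the pairing, and they are too few for a share under 0.05. The splits therefore do not exclude chance once the libraries are taken as paired. In cluster 8 the real count was 0, which each of the 35 splits reaches whatever the data (highest other 3), so the splits decide nothing there. The 10 splits of cluster 5 are too few for a share under 0.05 (real 73, highest other 7). In simulated data edgeR found 55 of 67 genes changed 2-fold in neural-lineage cells, 30 of 67 in cluster 5 and 13 of 67 in cluster 8, so many changes of this size are missed in those clusters, and GFP low replicates 2 and 3 held 293 and 516 neural-lineage cells.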

Other observations

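The values in this part were chosen after they were seen, and no test was planned for them beyond those of the gene lists and of single genes.

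The tumour's transgenes were found at different levels across clusters. Which sequence the EGFRvIII feature covers is not given in the sources used here, so its levels describe UMIs given to that feature. EGFRvIII, by its name a truncated growth factor receptor, made up 1.16% of the UMIs of neural-lineage cells, at 10814 ± 1400 CPM in GFP high and 12122 ± 1893 CPM in GFP low (SD, n = 4; log2 -0.16, edgeR adjusted p = 0.446). Its level was 17150.0 ± 1942 against 23070.0 ± 4844 CPM in cluster 8 (3 GFP low libraries) and 8241 ± 1180 against 7969 ± 1025 CPM in the astrocyte-like class. Cluster 3, the smaller of the mature-oligodendrocyte-like clusters, had 5247 ± 292 against 2933 ± 390 CPM, in 2 libraries per fraction, beside 4771 CPM in immune cells. Its cells differed in quality, with a median of 23194 UMIs and 4.08% mitochondrial UMIs in GFP high against 3963 and 6.52% in GFP low. Cluster 4, the larger one, had 9695 ± 909 and 8840.0 ± 1931 CPM. No test between clusters was run on these levels, and the RNA found in immune cells is a background for the lower ones only if it is free RNA and was not taken up with tumour cells. Cluster 8 also had the highest mean of eGFP RNA among the classes, 514 ± 426 CPM in GFP high against 138.5 ± 99.5 in GFP low, with a spread nearly as large as the mean. In cluster 7 it was 61.1 ± 9.92 against 27.6 ± 12.9 CPM, beside Tdtomato at 3731 ± 208 against 2464 ± 752 CPM. In cluster 5 eGFP went the other way, at 9.53 ± 9.27 against 31.4 ± 21.2 CPM (3 GFP low libraries). These means rest on few eGFP UMIs. GFP high replicate 4 held 15 cells and 33796 UMIs in this cluster, and GFP low replicate 4 held 65332 UMIs.

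In cluster 8, led by Fxyd1, Igfbp5 and Art3 and by the BMP target genes Id3 and Id1, several lists had members mostly on the same side of 0. Of 28 AC-like genes, 23 lay above 0 in GFP high relative to GFP low (median log2 difference 0.85, 5 higher adjusted over the list alone). Of 30 quiescent stem cell and astrocyte genes, 24 lay above 0 (median 0.81, 4 higher and 1 lower adjusted over the list alone), as did 19 of 22 immediate early genes (median 0.83, 3 higher) and 21 of 22 lysosome genes (median 0.46, 6 higher). Of 28 OPC-like genes 22 lay below 0 (median -0.41), although the 1 member past the threshold adjusted over the list alone was higher, and 18 of 19 genes of cholesterol synthesis lay below 0 (median -0.50) with none past it. None of these members passed the edgeR test over all genes in this cluster, where 918 genes had an unadjusted p under the threshold, DESeq2 called 79, and leaving out GFP low replicate 1 gave 7 genes and GFP high replicate 2 gave 1. The difference between this cluster and the others was not tested.

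In the mature-oligodendrocyte-like class, of 19 glycolysis genes 6 fell, 1 rose and 12 did not pass (median -0.22, 8 and 1 adjusted over the list alone), and of 16 chromatin and histone genes 5 fell (median -0.25, 8 adjusted over the list alone). Of 18 antigen presentation genes 17 lay above 0 (median 0.43), with 1 past the threshold and 4 adjusted over the list alone. These list counts within the class were not recomputed with libraries left out. The fold changes of this class were set against those of all neural-lineage cells. Only genes called in neural-lineage cells entered, here 2675 of 10661, and the line was fitted through the origin. The slope was 0.877, against 0.722, 0.661, 0.541 and 0.42 in clusters 5, 8, 2 and 7, 0.436 in the proliferating class and 0.366 in the astrocyte-like class. These slopes were not tested against each other, and the genes were picked by the calls of the larger fit. Genes are not independent replicates, and the class is itself part of the population it is set against.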
